A study of Mus musculus with 4 samples.

How the data were processed

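The series measured contacts between RNAs in mouse spermatogonial stem cells by RIC-seq, a method that fixes RNA and protein in cells with formaldehyde, cuts the RNA, joins RNA ends that lie close together and reads the joined (chimeric) fragments. Per the labels, cells were fixed in formaldehyde, RNA was cut with micrococcal nuclease, ends were marked with pCp-biotin and ligated in place, and strand-specific libraries were made. The samples were 2 control libraries and 2 libraries labelled differentiation. The inducer and the duration of differentiation were not given in the sources used here.

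The deposited table held 1 whole-number count of chimeric reads per pair of RNAs and library, with no normalization. STAR and the mouse genome build GRCm38 were named, without a role or version, per the submitters' processing notes. The rules for calling a read chimeric, for duplicates and for reads over overlapping genes were not given in the sources used here. The table listed 56636 pairs of 13318 RNAs, of which 4836 joined an RNA to itself (within-RNA pairs) and 51800 joined different RNAs (between-RNA pairs). Every listed pair had a count of at least 1 in all 4 libraries, so pairs seen in only some libraries were not analysed here, and the totals below are those of shared pairs, not sequencing depth. The selection also removed any pair lost completely in either group. Of the 13318 RNA names, 12030 matched a symbol and 516 a synonym in a reference gene table of assembly GRCm38.p6, and 772 stayed unmatched. That table gave the coordinates (1-based) and gene classes. Near-identical RNAs (histones, pseudogenes, the Gm10800 family) and overlapping genes can share reads, so their values are uncertain. Among 28927 pairs with a summed count of at least 20, 2164 (7.48%) had the same counts in all 4 libraries as another pair of the same partner.

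Total counts were 1209031 and 1400011 in the controls and 793129 and 1155923 in the differentiation libraries. The labels did not say whether libraries came from separate cultures, so p-values measured only the spread between these libraries, which may be technical. Wilson intervals at 95% were given for single-library shares, and 95% exact intervals for ratios resting on few counts. Reads carried no molecular identifiers that were used here, so these intervals covered counting error only.

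Pairs were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and a low-count filter (filterByExpr, minimum count 5, minimum total 10), two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The same test was run on the summed count of all pairs of an RNA (its contact total), with a within-RNA pair counted once. A between-RNA pair enters 2 totals, so totals were not independent of each other. Contact totals measure chimeric reads, and can move with the RNA level as well as with its contacts. The biological coefficient of variation was 24.9% over pairs and 18.7% over RNAs. Levels were given as scaled counts (CPM as given by edgeR, mean ± SD, n = 2), and changes as log2 of differentiation over control with the standard error (SE) of the fit.

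Gene lists fixed before the data were examined (24 lists) were tested on contact totals with camera of limma 3.58.1 at a preset correlation of 0.01. Adjustment ran over the 23 lists with at least 3 tested members. Camera with an estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes, stood beside it. With 2 libraries per group an exact two-sided permutation test cannot go below p = 0.333. It was used for shares of counts and for the number of distinct pairs after thinning each library to 793129 counts.

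The rule for named genes was also fixed beforehand. It took the 3 study genes with up to 3 of their pairs of largest summed count, and the 10 largest rises and 10 largest falls past the threshold with no overlap between groups. It added the 5 features with most counts, and up to 4 called members per list by adjusted p, or up to 2 tested members by mean count where none was called. Zhx3-Chd6, Neat1-Rps3, Sparc and the genes named under other observations (Dnah8 and others) were chosen after their values were seen.

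Alternatives were RLE scaling, column totals only, no filter, the default filter (minimum count 10, total 15), replicate number as a block, between-RNA pairs only and leaving out the 10 largest pairs. Further ones left out each library in turn, or the 20 RNAs named or classed as mitochondrial or ribosomal RNA (0.217% to 0.345% of the counts of a library). Gm42418 and Gm26917, whose pairs held 19.4% to 24.5%, were not among those 20, so leaving out the 20 does not test their weight. Others used DESeq2 1.42.0, a robust dispersion or an adjusted p under 0.1. With 1 library left out, the lone library of its group was assumed to vary like the other group. Chosen after seeing the data were keeping 1 of each set of identical pairs, and leaving out the pairs of Neat1, of Gm42418 and Gm26917, or of the Gm10800 group. The group left out was Gm10800, Gm10718, Gm21738, Gm10722, Gm10717 and Gm10801. Column totals moved the median log2 change of all tested pairs from 0.02 to −0.12 and that of all RNAs to 0.16, so changes hold relative to TMM scaling.

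The tests were tested on simulated data with known changes, drawn for 30559 pairs and 10874 RNAs of this comparison. Shares are of the simulated changes that kept a count in every library and could be tested. Among such pairs, 4.08% of those changed 2-fold, 33.3% changed 4-fold, 85.1% changed 8-fold and 95.0% changed 16-fold were recovered. For RNAs the shares were 20.4%, 66.0%, 95.9% and 100.0%. Of 50 pairs changed 16-fold only 40 could be tested, and 38 were recovered. Of 50 RNAs changed 16-fold 45 could be tested, and 45 were recovered. False calls were 6 of 102 for pairs and 6 of 141 for RNAs. For gene lists, a 2-fold shift put into the cytosolic ribosomal protein list was called, and 0 of the other 22 lists were called by camera. The simulated RNAs were drawn independently of each other, so this does not test camera where list members move together. In the data the estimated correlations ran from −0.46 (study genes) to 0.27 (translation factors). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables, shares and permutations, and matplotlib 3.10.9 for plots.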

Results

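RNA contacts were compared between 2 control and 2 differentiation libraries of mouse spermatogonial stem cells, the cells of the testis that renew themselves and give rise to sperm. The title of the series names the long noncoding RNA Gm16751, the zinc-finger and homeobox gene Zhx3 and the ribosomal protein RPS3. Contacts of the RNAs of these 3 genes were therefore looked at first. The counts join RNA to RNA, so contacts of the RPS3 protein were not measured. Total chimeric counts over the pairs shared by all libraries were 1209031 and 1400011 in the controls and 793129 and 1155923 in the differentiation libraries.

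The contact of Zhx3 with Gm16751 rose 3.06-fold with differentiation, from 11.6 ± 0.227 to 35.95 ± 3.43 CPM (log2 change 1.61, SE 0.43, adjusted p = 0.0376). Contacts within Zhx3 RNA itself rose alike, from 59.0 ± 8.35 to 179 ± 2.35 CPM (1.601, SE 0.26, adjusted p = 0.00132). Contacts of Zhx3 with Chd6, a chromatin remodeller gene, fell from 13.2 ± 0.405 to 1.19 ± 0.328 CPM (−3.40, SE 0.82, adjusted p = 0.0216). This pair held only 2 counts in the differentiation libraries, the fewest a listed pair can have. The ratio of control over differentiation was 11.5 with a counting interval of 2.95 to 98.9. Contacts of Rps3 RNA, which encodes a protein of the small ribosomal subunit, with the paraspeckle RNA Neat1 fell from 35.97 ± 7.97 to 2.38 ± 0.656 CPM (−3.91, SE 0.61, adjusted p = 9.75e-04), on 4 differentiation counts (ratio of control over differentiation 15.9, counting interval 6.01 to 59.6). Beyond the change within Neat1 itself this fall had an excess of −1.86, which did not pass (adjusted p = 0.238). Zhx3 lay on chromosome 2 at 160770447 to 160872990 and Chd6 at 160946978 to 161109086, 74.0 kb apart, and Rps3 on chromosome 7 at 99477896 to 99483709 (GRCm38.p6). The location of Gm16751 was not used here.

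Of 10 listed Zhx3 pairs 7 could be tested, and 2 rose and 1 fell. Of 63 Rps3 pairs 38 could be tested, and only the pair with Neat1 passed. Its pairs of largest count did not, with log2 changes of −0.62 with Gm26917 (adjusted p = 0.178), 0.28 with Gm42418 and 0.43 with the ion exchanger RNA Slc9a9. The pair of Gm42418 with Zhx3 had a change of 0.06, which turned to −0.07 under column totals. Of 4 Gm16751 pairs only that with Zhx3 had counts enough for a test, and those with Gm26917 (5, 7, 2 and 3 counts) and Gm42418 (4, 9, 1 and 2 counts) did not. Over all pairs, the contact total of Zhx3 rose (0.70, SE 0.18, adjusted p = 0.0244; 96.2 ± 7.89 to 156 ± 0.195 CPM). The totals of Gm16751 (0.41, adjusted p = 0.462) and Rps3 (−0.34, adjusted p = 0.190) did not pass. The Zhx3-Gm16751 call was lost without control 1 (adjusted p = 0.144), control 2 (0.210) or differentiation 1 (0.0576), under column totals (0.0577) and with DESeq2 (0.0592), and over 19 alternatives the adjusted p ran from 0.0225 to 0.210. The Zhx3 total was lost without control 1 (0.156) or control 2 (0.305) and over between-RNA pairs only (0.710), and Zhx3-Chd6 was lost without differentiation 2 (0.0955; 0.00683 to 0.0955 over 19 alternatives).

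**Figure D1:**
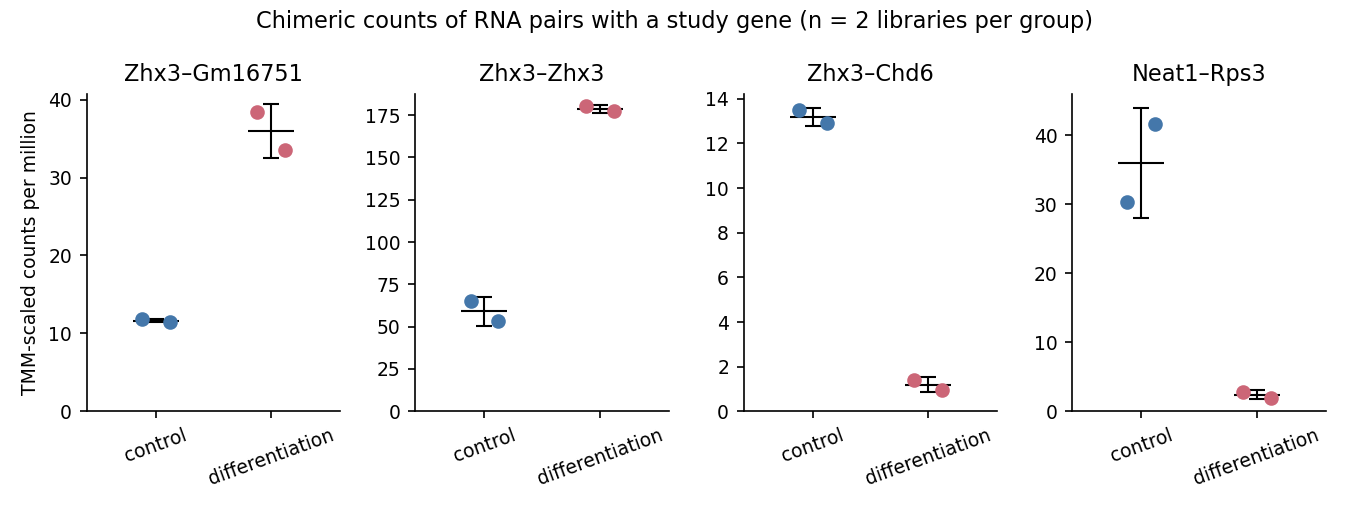
TMM-scaled CPM of 4 RNA pairs with a study gene, with 1 point per library, the mean as a long line and ± 1 SD as bars (n = 2 per group, y axes from 0). Zhx3-Gm16751 went from 11.6 to 35.95 and Zhx3-Zhx3 from 59.0 to 179, while Zhx3-Chd6 went from 13.2 to 1.19 and Neat1-Rps3 from 35.97 to 2.38.

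Neat1, the long noncoding RNA that builds paraspeckles, had the largest change among the 5 RNAs with most counts. Its contact total fell 5.07-fold, from 44320.1 ± 4395 to 8750.5 ± 2124 CPM (−2.34, SE 0.18, adjusted p = 3.07e-05), and its within-RNA pair fell from 38908 ± 3153 to 9140.5 ± 2381 CPM (−2.09, SE 0.15, adjusted p = 6.14e-07). Neat1 pairs held 5.89% and 6.73% of control counts and 1.59% and 1.16% of differentiation counts. Of 801 tested pairs of Neat1 with another RNA, 268 fell, the rest did not pass, and the median was −1.99. These were 43.8% of all between-RNA pairs that fell. Steep falls on more than 3 differentiation counts were those with Brinp3 (−4.43, SE 0.26, adjusted p = 3.44e-08; 524 ± 20.1 to 24.3 ± 1.84 CPM), the calpain gene Capn1 (−4.35, SE 0.34, adjusted p = 1.18e-06), the Cdc42 effector gene Cdc42ep2 (−4.47) and Auts2 (−4.77). Neat1 lay on chromosome 19 at 5824708 to 5845480, Cdc42ep2 72.1 kb and Capn1 143 kb from it, and Brinp3 on chromosome 1. Contacts with Nfia, Sparc, Cers6 and Zfp704 were also among the 10 largest falls, by −4.45, −4.63, −4.28 and −4.25, each on 2 or 3 differentiation counts. The fewest that a listed pair can have is 2. For Sparc-Neat1 the ratio of control over differentiation was 27.4 with a counting interval of 7.35 to 230.3, and for Neat1-Nfia it was 23.3 (7.74 to 114.6). For Neat1-Cers6 it was 21.0 (5.57 to 177.2), and for Neat1-Zfp704 20.3 (6.73 to 100.4). The neighbouring nuclear-speckle RNA Malat1, 22.04 kb from Neat1, fell 2.12-fold (−1.09, SE 0.15, adjusted p = 0.00106), and 90 of its 1487 tested partner pairs fell. Without control 2 the fallen pairs numbered 155 for Neat1 and 31 for Malat1, and the Malat1 total lost its call (adjusted p = 0.114). Without differentiation 1 the fallen Malat1 pairs numbered 146.

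**Figure D2:**
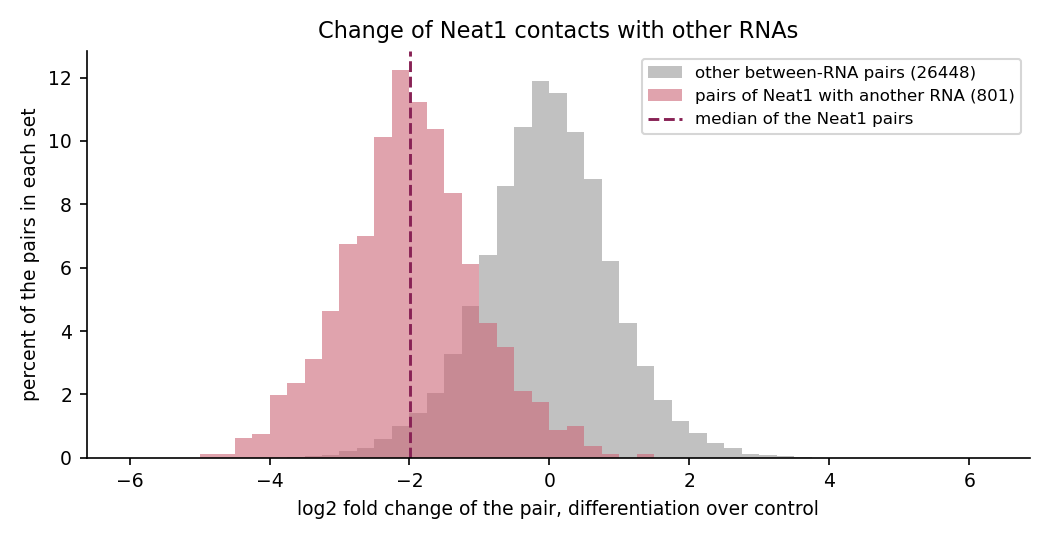
Distribution of log2 changes (x axis, differentiation over control) of the 801 tested pairs of Neat1 with another RNA and of the other between-RNA pairs, as percent of the pairs in each set (y axis). The median of the Neat1 pairs, drawn as a dashed line, was −1.99.

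Across all RNAs, 902 pairs rose and 760 fell of 31688 tested (6551 had an unadjusted p under 0.05). Among contacts within an RNA more rose than fell, with 548 higher and 148 lower of 4439 tested. Among contacts between RNAs 354 rose and 612 fell of 27249 tested, and 268 of those that fell held Neat1. Without its pairs 63.6% of all changed pairs were higher. Of the 10 largest rises 8 were within single RNAs. The Rsph1 pair, from a radial spoke gene of cilia and flagella, rose from 4.55 ± 1.67 to 325 ± 55.3 CPM (6.10, SE 0.35, adjusted p = 3.44e-08). Mroh4 went from 2 counts to 239, a ratio of 176 with a counting interval of 48.3 to 1466, and Ccdc60 from 2 to 92 counts, a ratio of 67.9 (18.3 to 569). Poteg with itself, from 2 to 88 counts, had a ratio of 64.97 (17.5 to 545), and Srgn one of 26.6 (6.84 to 228). The within-RNA pairs of Mroh4, Ccdc60, Poteg and Srgn each had 1 count per control library, the lowest a listed pair can have. Their intervals do not allow for that. Spag17, which encodes a central-pair protein of the axoneme, rose by 4.61, Pebp4 by 4.85 and March10 by 4.43, and Poteg also rose with the transcript RP23-202K1.1, by 6.03. Ybx2, a germ-cell RNA-binding protein gene, rose in contact with Gm42418 on 3 control counts, at a ratio of 36.9 (12.2 to 183). Among falls outside Neat1 were Brinp3 with Capn1 (−4.38) and Zg16 with itself (−4.22). Of the 5 pairs with most counts, Sparc with itself rose (0.54, SE 0.14, adjusted p = 0.0269), a call lost without control 1 (0.328), without control 2 (0.444) and under column totals (0.105). The 3 pairs of Gm10800 among them varied widely between replicates and did not pass. Column totals moved the share of higher calls among changed pairs from 54.3% to 38.4%, with 392 higher and 189 lower within RNAs and 234 and 814 between them. Without control 2, changed pairs numbered 643 (298 higher, 345 lower), without differentiation 1 they numbered 2533 (1454 higher), and without control 1 the higher ones numbered 591. Within RNAs the higher pairs numbered 361 without control 1, 197 without control 2 and 885 without differentiation 1, and the lower ones 66 without control 2 and 228 without differentiation 1. Between RNAs the higher pairs numbered 230, 101 and 569 in the same order, and the lower ones 279 without control 2.

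For contact totals, 598 RNAs rose and 742 fell of 10993 tested (2970 had an unadjusted p under 0.05). Rsph1 rose 56.2-fold, from 3.17 ± 1.21 to 185 ± 29.2 CPM (5.81, SE 0.31, adjusted p = 2.82e-06), Poteg by 5.74 (SE 0.36, adjusted p = 1.14e-05) and Spag17 by 4.33 (SE 0.38, adjusted p = 4.91e-05). Rises from 2 or 3 control counts, where 2 is the fewest possible here, were those of Mroh4 (ratio 144, counting interval 39.5 to 1197) and Ccdc60 (55.5, 14.9 to 465). Others were Srgn (21.7, 5.59 to 186), which encodes the proteoglycan serglycin, Lrriq1 (16.1, 5.12 to 81.3) and the transporter gene Abcc12 (17.5, 4.42 to 151.3). March10, a ubiquitin ligase gene, and the chemokine gene Pf4 rose by 4.16 and 4.04. The totals of Rsph1, Mroh4, Ccdc60, Spag17, Srgn, March10 and Zg16 held only the counts of their within-RNA pairs. These totals repeat the pair results and hold no listed contact with another RNA. The largest falls were those of Cdc42ep2 (−4.76, SE 0.39, adjusted p = 3.52e-05), Zg16 (−4.52), Capn1 (−4.16) and Brinp3 (−4.07). Pairs with Neat1 held 100% of the control counts of Cdc42ep2, 86.7% of those of Capn1 and 87.4% of those of Brinp3. Without the Neat1 pairs the changes of Capn1 and Brinp3 were −2.65 and −2.26. Both rest largely on their shared Brinp3-Capn1 pair, with 162 control and 5 differentiation counts, so they are not separate results. Of 1543 and 74 counts of Brinp3, 1348 and 42 were with Neat1, and of 1600 and 71 of Capn1, 1387 and 44 were. A fall of either RNA outside these pairs was not tested. The potassium channel gene Kcnd2 (−3.61), Scara5 (−3.05), Prss36 (−3.01) and the growth factor gene Pdgfd (−2.96) also fell, as did Tha1 (−3.20) and Inha, on 3 differentiation counts (ratio of control over differentiation 9.12, counting interval 2.86 to 46.5). Of the 5 RNAs with most counts, Gm26917 fell (−0.50, SE 0.13, adjusted p = 0.0296), a call lost without control 1 (0.183) or control 2 (0.491), with RLE scaling (0.0522) and under column totals (0.168). Gm42418 (−0.26), Slc9a9 (−0.29) and Gm10800 (1.05, adjusted p = 0.260) did not pass. Gm10800 did pass in an alternative that kept all libraries. Its log2 ratio of replicate 1 to replicate 2 was 1.85 in controls and 1.94 in differentiation libraries, so its missing call depends on the fit used. Without control 1 changed RNAs numbered 294 (107 higher, 187 lower), without control 2 they numbered 129 (46 and 83), and without differentiation 1 they numbered 2103 (1081 higher). Srgn, Pf4, Lrriq1, Abcc12, Tha1 and Inha lost their calls without control 1 or control 2, at adjusted p up to 0.115, 0.1003, 0.141, 0.146, 0.101 and 0.103, and March10 without control 2 (0.0683). Over between-RNA pairs only, 9 of the 10 largest rises could not be tested, and Prss36 lost its call (−2.05, adjusted p = 0.0730). Column totals moved the share of higher calls from 44.6% to 63.0%.

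Some genes of meiosis and of the germ line gained contacts. In the meiotic prophase list 7 of 15 tested RNAs rose (10 adjusted over the list alone), with a median of 1.28 (camera adjusted p = 1.61e-10; adjusted p = 0.402 with an estimated correlation). Sycp1, the transverse filament gene of the synaptonemal complex, rose from 24.2 ± 5.03 to 171 ± 35.7 CPM (2.83, SE 0.24, adjusted p = 4.43e-05). The meiotic recombinase gene Dmc1 rose by 1.87 (SE 0.18, adjusted p = 8.55e-05), the meiotic cohesin gene Smc1b by 2.20 and the chromosome-axis gene Hormad1 by 2.86. In the germ cell identity list 3 of 11 rose (6 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 4.81e-05; adjusted p = 0.402 with an estimated correlation). They were the piRNA-pathway genes Tdrd9 (2.17, SE 0.23, adjusted p = 1.78e-04), Mov10l1 (1.39) and Tdrd5 (1.61). Of 65 histone RNAs 32 rose (43 adjusted over the list alone), with a median of 1.26 (camera adjusted p = 1.87e-21; adjusted p = 0.402 with an estimated correlation). Hist1h2ba, the testis-enriched H2B, rose 6.64-fold (2.73, SE 0.21, adjusted p = 3.27e-05), Hist1h4b by 2.00, Hist1h4c by 1.58 and Hist1h2bl by 1.62. Histone genes are near-identical, so single members are uncertain. Among 6 X-linked spermatogonial RNAs, Tex16 rose (2.00, SE 0.22, adjusted p = 2.35e-04), 3 rose adjusted over the list alone, and the median was 0.82 (camera adjusted p = 0.00242; adjusted p = 0.455 with an estimated correlation). Under column totals 3 of the 6 rose. In the same libraries the medians of the Sertoli and fibroblast marker lists were −0.68 and −0.55. The histone calls numbered 11 without control 1, and without control 2 they numbered 5, the meiotic calls 3 and the germ cell calls 1. The X-linked calls numbered 3 without differentiation 1 and 2 without differentiation 2. Hormad1 (adjusted p = 0.0690) and Mov10l1 (0.0920) lost their calls without control 2 and Tdrd5 without either control (up to 0.278), and over between-RNA pairs only Smc1b lost its call (0.254).

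Some genes of stem cell self-renewal lost contacts, as did some Sertoli cell and fibroblast markers. In the self-renewal list 4 of 13 tested RNAs fell (4 lower and 1 higher adjusted over the list alone), with a median of −0.81 (camera adjusted p = 5.02e-04; adjusted p = 0.402 with an estimated correlation). Shisa6, a marker of undifferentiated spermatogonia, fell 4.83-fold, from 591 ± 66.7 to 123 ± 25.3 CPM (−2.27, SE 0.19, adjusted p = 3.52e-05). Gfra1, which encodes the GDNF co-receptor, fell by 1.20 on the log2 scale (SE 0.19, adjusted p = 0.00198), Zbtb38 by 1.11 and the transcription factor gene Foxo1 by 0.83. Of 10 Sertoli cell markers 4 fell (4 adjusted over the list alone), with a median of −0.68 (camera adjusted p = 0.00242; adjusted p = 0.455 with an estimated correlation). They were Clu (−1.26, SE 0.18, adjusted p = 0.00106), Gata4 (−1.002), the inhibin gene Inha and Wt1 (−0.53). Of 16 fibroblast and feeder markers 6 fell and 2 rose (the same counts adjusted over the list alone), with a median of −0.55 (camera adjusted p = 0.0212; adjusted p = 0.455 with an estimated correlation). The matrix genes Fbn1 (−1.39) and Col3a1 (−1.20) and the receptor gene Pdgfrb (−1.34) fell, and the matrix gene Tnc rose (1.21, SE 0.16, adjusted p = 6.34e-04). The 7 Leydig and peritubular markers had no called member and a median of −0.01 with a mean of 0.12 (camera adjusted p = 0.987), the median turned to 0.02 under RLE scaling and 0.16 under column totals, and Acta2 (−0.11, turning to 0.05 under column totals) and Myh11 (0.16) did not pass. Among immune markers only Itgam was tested (1.58, adjusted p = 0.293; −1.72 without differentiation 1). Without control 1 the calls numbered 2 for self-renewal, 1 for Sertoli and 1 lower and 1 higher for fibroblast markers, and without control 2 they numbered 1, 0 and 0. The self-renewal median was −0.48 without control 2, the fibroblast median −0.30 without control 1 and the Sertoli median −1.05 without differentiation 1. Shisa6 kept its call in all of these fits. Without control 2 the calls of Gfra1 (adjusted p = 0.0901), Clu (0.0657), Fbn1 (0.0776) and Tnc (0.0715) were lost. Zbtb38 (up to 0.0757), Foxo1 (0.221), Gata4 (0.2504), Inha (0.103), Col3a1 (0.111) and Pdgfrb (0.139) lost theirs without either control. The fibroblast list lost its call without control 1 (camera adjusted p = 0.102) and differentiation 2 (0.0599), and under column totals 3 of its RNAs fell. Wt1 lost its call without either control (adjusted p up to 0.413) and under RLE scaling and column totals.

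Some nuclear long noncoding RNAs and small nucleolar RNAs lost contacts. Long noncoding RNAs as a class went both ways, with 14 higher and 21 lower of 268 and a median of −0.13, against 14 and 11 with a median of 0.02 under column totals. The class median was −0.08 without control 1, −0.20 without control 2, −0.37 without differentiation 1 and 0.03 without differentiation 2. Of 27 nuclear and snoRNA-host long noncoding RNAs 11 fell (12 adjusted over the list alone), with a median of −0.62 (camera adjusted p = 4.31e-06; adjusted p = 0.455 with an estimated correlation). Besides Neat1 and Malat1, the imprinted RNAs Meg3 (−1.68, SE 0.17, adjusted p = 1.17e-04) and Airn (−1.32, SE 0.19, adjusted p = 0.00125) fell. Of 93 small nucleolar RNAs, which guide RNA modification, 11 fell (11 adjusted over the list alone), with a median of −0.23 (camera adjusted p = 0.0132; adjusted p = 0.455 with an estimated correlation). Snord13 fell by 1.14 on the log2 scale (SE 0.17, adjusted p = 0.00139), Snord14c by 0.86, Snord12 by 1.76 and Snord80 by 1.77. Under column totals 4 of the long noncoding and 5 of the small nucleolar RNAs fell. Without control 1 these calls numbered 4 and 1, without control 2 they numbered 2 and 0, without differentiation 2 the long noncoding calls numbered 6, and without differentiation 1 the nucleolar ones numbered 18 lower and 3 higher. Without control 2 Airn lost its call (adjusted p = 0.0765), as did Snord13 (0.0895) and the small nucleolar list (camera adjusted p = 0.0506). Snord14c, Snord12 and Snord80 lost their calls without either control (up to 0.119, 0.122 and 0.228). The list median was −0.35 without differentiation 2 and −0.07 under column totals. The list also lost its call over between-RNA pairs only (0.1998).

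Genes of growth and division gained contacts in part. Of 27 cell cycle RNAs 8 rose (11 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 6.47e-06; adjusted p = 0.455 with an estimated correlation). The condensin gene Smc4 rose 3.12-fold (1.64, SE 0.23, adjusted p = 0.00110), the spindle-checkpoint gene Bub1b by 1.19, the proliferation marker gene Mki67 by 1.12 and Kif20b by 1.45. Over all alternatives the change of Bub1b went down to 0.44 and its adjusted p up to 0.668, in fits that kept all libraries. Of 74 cytosolic ribosomal protein RNAs 15 rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 4.81e-05; adjusted p = 0.455 with an estimated correlation). Rplp1 rose by 1.06 (SE 0.18, adjusted p = 0.00315), Rpl36 by 1.12, Rps19 by 1.01 and Rps14 by 0.81, and under column totals 20 rose and 0 fell. Of 12 mitochondrially encoded RNAs 3 rose (5 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.0121; adjusted p = 0.470 with an estimated correlation), led by mt-Tm (1.38, SE 0.22, adjusted p = 0.00192) and mt-Nd5 (0.87). Of 19 chaperone RNAs 3 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0311; adjusted p = 0.476 with an estimated correlation). Hsp90aa1 rose by 1.21 (SE 0.18, adjusted p = 0.00124), Hspd1 by 0.96 and Tcp1 by 0.72, and Hspa8 fell (−0.55), a call lost under column totals. All named genes here lost their calls without control 2, as did all but Smc4 and mt-Tm without control 1, with adjusted p up to 0.0757 for Smc4, 0.131 for Rplp1, 0.105 for mt-Tm and 0.272 for Hspd1. Hspd1, Tcp1 and Hspa8 also lost theirs without differentiation 2. Without control 1 the calls numbered 1 for cell cycle, 1 for mitochondrial and 0 for ribosomal protein and chaperone RNAs, and without control 2 all were 0. Without differentiation 1, 31 ribosomal protein, 8 chaperone and 5 mitochondrial RNAs rose, and without differentiation 2, 2 chaperone RNAs did. The mitochondrial list lost its call without differentiation 2 (median 0.26, camera adjusted p = 0.135), and the chaperone list without control 1 (0.0769) and differentiation 2 (0.254). The chaperone median was 0.59 without differentiation 1.

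**Figure D3:**
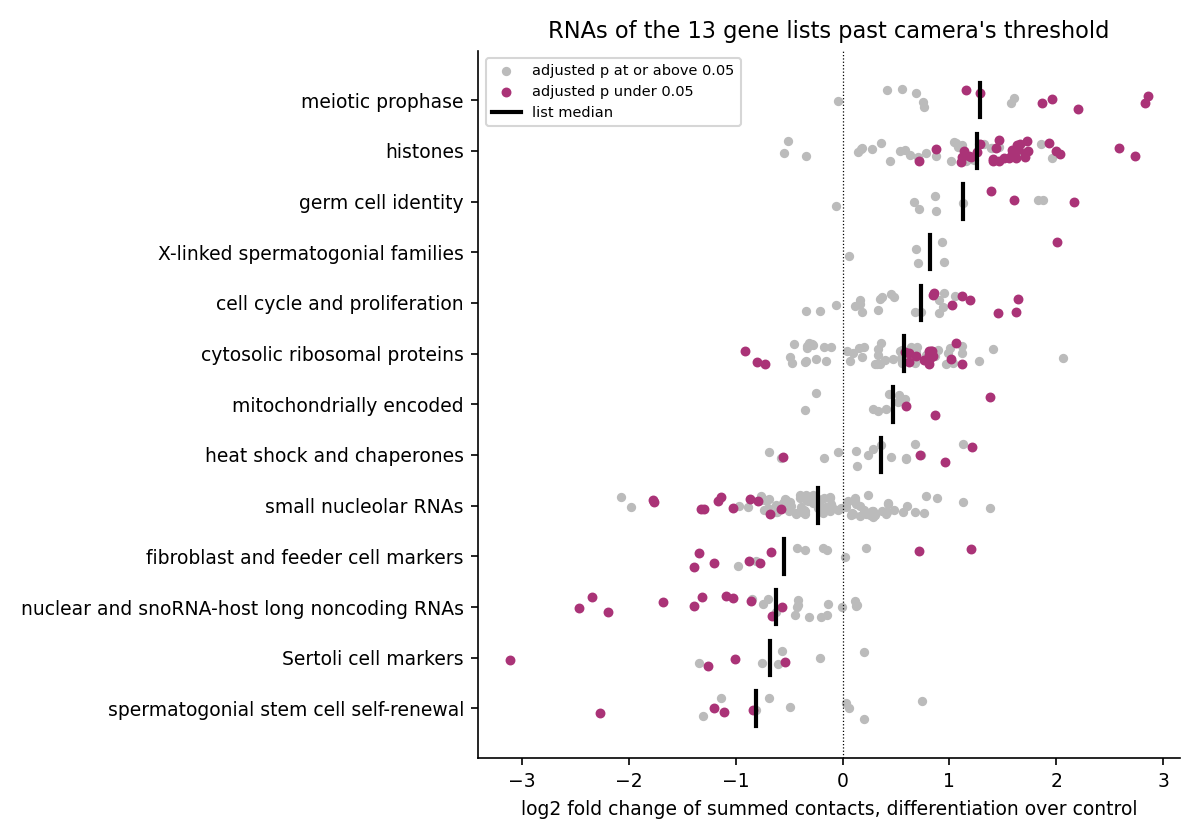
Log2 change of the contact total (x axis, differentiation over control) of each tested RNA in the 13 gene lists past camera's threshold, in colour where the adjusted p was under 0.05, with the list median as a black line. Medians ran from −0.81 for stem cell self-renewal to 1.28 for meiotic prophase.

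In all, 13 of 23 lists passed camera, none passed with an estimated correlation (the lowest adjusted p was 0.402), and 3 passed fry, namely self-renewal (0.0211), histones and germ cell identity (both 0.0489). The remaining lists did not pass camera, and their members moved both ways or little. Of 11 RNAs of differentiating spermatogonia 1 rose and 1 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.742), with the transcription factor gene Dmrt1 at −1.40 (SE 0.26, adjusted p = 0.00495) and Ptma at 0.67. Of 9 retinoic acid response RNAs 1 rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.949). Cyp26a1, which encodes an enzyme that degrades retinoic acid, was at 2.31 (adjusted p = 0.0447). Among 27 spliceosomal, 7SK, 7SL and RNase RNAs 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 1.00), with the Y RNAs Rny3 (−1.58) and Rny1 (−1.11) lower and Rprl3 (0.91) and the RNase P RNA Rpph1 (0.68) higher. The list as fixed also held Gm26917, which was the remaining fall (−0.50). Of 24 translation factor RNAs 4 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.145, and 0.0136 without differentiation 1), including the poly(A)-binding protein gene Pabpc1 (1.07), the cap-binding protein gene Eif4e (1.00), Eif5a (0.75) and Eif4g3 (−0.59). Of 15 glycolysis RNAs 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.164), the glucose transporter gene Slc2a3 (1.38), Eno1 (−1.25) and Pfkl (−1.43). Over all alternatives the change of Slc2a3 went down to 0.56 and its adjusted p up to 0.202, in fits that kept all libraries. Of 22 GDNF, FGF and KIT signalling RNAs 2 fell (2 adjusted over the list alone; camera adjusted p = 0.384), Gfra1 and the early-response gene Egr1 (−1.13). Of 23 chromatin RNAs 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.409), with the DNA demethylase genes Tet3 (−0.96) and Tet2 (−1.07) lower and Uhrf1, needed to maintain DNA methylation, higher (1.09). Of 38 splicing factor RNAs only Luc7l3 was called (−0.99, adjusted p = 0.0422; 0 adjusted over the list alone; camera adjusted p = 0.883), and of the 3 study genes Zhx3 alone (1 adjusted over the list alone; camera adjusted p = 0.538). Medians of the retinoic acid, small RNA, splicing factor and signalling lists, −0.04 each, turned to 0.12, 0.11, 0.12 and 0.11 under column totals. The small RNA, glycolysis and signalling lists each kept 1 lower call without control 1 and the others 0, and without control 2 all had 0. Without differentiation 1, 7 translation factor and 6 splicing factor RNAs rose, 2 rose in each of the signalling and chromatin lists, and 4 glycolysis RNAs fell. Without differentiation 2, 2 RNAs of differentiating spermatogonia rose and 3 fell, 3 splicing factor and 2 retinoic acid RNAs fell, and 1 signalling RNA fell. Of the genes named here all but Rny3 and Pfkl lost their calls without control 1 (Dmrt1 up to 0.106, Cyp26a1 up to 0.336, Pabpc1 up to 0.0895), save Gfra1, and all lost them without control 2. Luc7l3 also lost its call without differentiation 1, Cyp26a1 and Egr1 without differentiation 2, and under column totals Tet2, Egr1, Eif4g3 and Luc7l3 lost theirs.

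The share of counts from contacts within an RNA overlapped between the groups. It was 48.9% (95% Wilson interval 48.8 to 49.0) and 49.4% (49.3 to 49.5) in the controls and 47.7% (47.5 to 47.8) and 52.9% (52.8 to 53.0) in the differentiation libraries. Means were 49.1 ± 0.349% and 50.3 ± 3.73% (n = 2 each; exact two-sided permutation test, p = 1, smallest possible 0.333). The difference of 1.14 percentage points became −1.49 without differentiation 2 and 3.78 without differentiation 1. Without the 10 largest pairs the groups no longer overlapped, at 47.7% and 47.1% against 49.3% and 52.7% (difference 3.65 points; exact two-sided permutation test, p = 0.333). Nor did they without the Gm10800 group, at 50.8% and 49.9% against 52.2% and 54.2% (2.83 points; exact permutation p = 0.333). After thinning to 793129 counts, 52335 ± 714 distinct pairs were counted per control and 54632 ± 2834 per differentiation library (exact two-sided permutation test, p = 0.667). The smallest library keeps all 56636 pairs by construction, so these numbers do not measure the breadth of contacts.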

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

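The alternatives that left out identical pairs, or pairs of Neat1, of Gm42418 and Gm26917, or of the Gm10800 group, were chosen after seeing the data. Where not stated otherwise, the cause of a change was not tested. All 24 named pairs and 101 named RNAs past the threshold kept their direction in every fit that left out a library. Of all calls, 1661 of 1662 pairs and 1340 of 1340 RNAs had no overlap between groups. Leaving out 1 library could therefore hardly reverse them, and the kept direction is no test of robustness. Of the 24 pairs, 22, 22, 23 and 24 stayed past it without control 1, control 2, differentiation 1 and differentiation 2, and of the 101 RNAs 49, 33, 100 and 95. With 1 library left out, changed pairs ran from 643 to 2533 (298 to 1454 higher, 345 to 1079 lower), changed RNAs from 129 to 2103 (46 to 1081 higher, 83 to 1022 lower) and lists past camera from 10 to 14. There were 759 changed pairs (289 higher, 470 lower) over between-RNA pairs only, 1104 (402 lower) without Neat1, and 568 higher without Gm42418 and Gm26917. Over between-RNA pairs only, 85 of the 101 named RNAs could be tested, and 71 kept their calls. Without Gm42418 and Gm26917, 100 could be tested, and 87 kept theirs. At an adjusted p under 0.1, 2983 pairs changed (1622 higher, 1361 lower) and 919 RNAs rose. Under column totals 458 RNAs fell. With replicate number as a block 942 RNAs rose, against 598 without it, and all 1662 pairs and 1340 RNAs kept their calls; same-numbered libraries had correlated deviations of 0.0189 over pairs and 0.141 over RNAs, and with 2 pairs of libraries and no label that ties them the numbers were not taken to pair the libraries. DESeq2 shared 1275 pairs and 1024 RNAs with edgeR, with no adjusted p for 18431 pairs and 3836 RNAs. No result past the threshold reversed, which for pairs and RNAs was nearly fixed in advance where 1 library was left out. Of the 179 results followed through the alternatives 13 others reversed, and the difference in within-RNA share turned to −1.49 without differentiation 2. Under column totals the reversed log2 values were 0.12 for retinoic acid response, 0.16 for Leydig and peritubular markers, 0.11 for small nuclear and RNase RNAs, 0.12 for splicing factors, 0.11 for GDNF, FGF and KIT signalling, −0.0722 for Gm42418-Zhx3 and 0.0542 for Acta2, and under RLE scaling 0.0201 for Leydig markers. Over between-RNA pairs only they were −0.0267 for differentiating spermatogonia, 0.11 for retinoic acid response, 0.17 for Leydig markers, 0.12 for small nuclear RNAs, 0.0627 for Acta2 and −0.17 for Sparc, which was at −0.34 without the 10 largest pairs. Leydig markers were at 0.16 with identical pairs kept once, 0.0517 without Gm42418 and Gm26917 (small nuclear RNAs 0.0778) and 0.0066 without the Gm10800 group. With 1 library left out the ranges were −0.22 to 0.14 for retinoic acid response, −0.11 to 0.14 for Leydig markers, −0.0798 to 0.0474 for small nuclear RNAs, −0.19 to 0.0345 for splicing factors, −0.34 to 0.33 for Gm42418-Zhx3, −0.0544 to 0.73 for Gm42418-Rps3, −0.0015 to 2.54 for Gm21738-Gm10800, −0.18 to 2.25 for Gm10800 and −1.72 to 2.59 for Itgam. Counts per pair limit what can be seen: simulated 2-fold changes were recovered for 4.08% of tested pairs and 20.4% of tested RNAs.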

Other observations

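The gene lists and genes of the opening paragraphs, and all tests weighed here other than the test of overlapping loci, that of a like Neat1 loss for every partner and that of a replicate-number batch, were chosen after the results were seen. Some genes of the axoneme, the motile core of cilia and sperm tails, gained contacts. Of 60 tested axonemal RNAs 23 rose and 1 fell, with a median log2 change of 0.85 (camera adjusted p = 9.67e-21 over 3 added lists; adjusted p = 0.0414 with an estimated correlation). The dynein heavy chain genes Dnah8 (3.05, SE 0.16, adjusted p = 2.82e-06) and Dnah17 (3.03), Cfap70 (3.04) and Ccdc39 (2.77) were among them, besides Rsph1 and Spag17. Without control 1 the rising members numbered 15 and without control 2 they numbered 11, and the list's p with an estimated correlation lay between 0.157 and 0.173 with any 1 library left out. Of 24 tested spermatocyte-to-spermatid RNAs 8 rose, with a median of 0.59 (camera adjusted p = 1.62e-07; adjusted p = 0.0414 with an estimated correlation). They included Catsperg1 (2.24) and Catsperg2 (2.25) of the sperm calcium channel, the transcription factor genes Rfx2 (2.20) and Mybl1 (3.19), Ybx2 (3.54) and Spata16 (3.17). Control counts were 33 and 58 for Catsperg1 and 28 and 55 for Catsperg2. Differentiation counts were 148 and 203 against 139 and 182. Whether these genes share reads was not tested, so they may not be separate rises. Without control 1 the rising members numbered 5, with a median of 1.11, without control 2 they numbered 4, without differentiation 1 the median was 0.88, and the p with an estimated correlation lay between 0.157 and 0.175 with any 1 library left out. Mybl1 lost its call without either control (adjusted p up to 0.0985) and Spata16 without control 2 (0.0855), and Ybx2 without pairs of Gm42418 and Gm26917 (0.105). Of 14 basement membrane RNAs only Lamb1 fell (−1.07, adjusted p = 0.0295; up to 0.296 without either control or differentiation 2), and the list did not pass (camera adjusted p = 0.124; 0.243 with an estimated correlation).

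Of 734 pseudogene RNAs, 70 rose and 2 fell, with a median of 0.59, against 472 and 672 of 9151 protein-coding RNAs, with a median of −0.05 that turned to 0.11 under column totals. Without control 1 the rising pseudogenes numbered 3, without control 2 they numbered 1, and without differentiation 1 they numbered 154. Protein-coding RNAs numbered 93 higher and 167 lower without control 1, 42 and 77 without control 2, and 837 and 908 without differentiation 1. Pseudogenes can share reads with their parent genes, so these values are uncertain.

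That axonemal genes rose as a set beyond the named largest rises was a hypothesis from the same data. Without those genes the median of the 56 other axonemal RNAs was 0.76 (camera adjusted p = 6.59e-15; 0.0414 with an estimated correlation), and 19 of them rose. Without every gene named in these texts, 14 of 51 rose and 1 fell, with a median of 0.62 (camera adjusted p = 9.68e-09; 0.171 with an estimated correlation). With any 1 library left out that median lay between 0.60 and 0.97, and 4 to 15 RNAs rose. A rise of many members stays a hypothesis, since the list was written after the rises were seen, and it does not tell a higher RNA level from more contacts per RNA.

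The contact total of Neat1 fell by 2.34 on the log2 scale, and the tables argue against scaling or a few dominant pairs, since the change nearest to 0 over 18 settings was −2.11 (highest adjusted p = 0.0128). Fibroblast and feeder markers moved less than Neat1, with a median of −0.55 (quartiles −0.90 and −0.10, and −0.67 to −0.30 over all alternatives). Of 16 markers 6 fell, the steepest Fbn1 at −1.39, and 2 rose. This met the bound used, but that bound was settled after these values were known. A first, stricter wording (a gap to the midpoint of the Neat1 change wider than the quartile spread) was not met. Fewer fibroblast or feeder cells therefore stay open as a cause. Sertoli markers also had a lower median (−0.68), and a loss of those cells was not tested. A lower Neat1 level that acts alike on every partner met its bound, written beforehand, as 3 of 801 pairs (0.375%) departed from the within-RNA change, but 12.4% did so at an unadjusted p under 0.05, 15 pairs (1.87%) departed without differentiation 2 and 5 without either control, and single pairs give little power, so it was left open for that later reason. For the 3 departing pairs (Brinp3, Capn1 and Cdc42ep2, all lower) such a loss alone is argued against, with an excess nearest to 0 of −2.26 (highest adjusted p = 0.0201 over all 801 pairs), and each departed with any 1 library left out (nearest to 0 −1.86, highest adjusted p = 0.0397). Brinp3 and Capn1 also fell in contact with each other (−4.38), so their 2 Neat1 pairs may not be separate support. The within-RNA change entered these tests as a fixed value without its SE of 0.15, so their p-values may be too small. No RNA level was measured, and the within-RNA pair that stood in for it is itself a contact. A lower Neat1 RNA level on differentiation may account for most pairs, but it cannot be told apart from fewer contacts per Neat1 RNA. Differentiation itself stays open as an untested explanation.

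Gm10800 and 11 RNAs like it, a wider set than the group left out in the alternatives, were far higher in both libraries numbered 1 than in those numbered 2. Mean log2 ratios were 1.85 in controls and 1.95 in differentiation libraries. The ratios hardly differed between the 12 RNAs (SD 0.0990 or less), which is consistent with reads shared between near-identical sequences. With group as a term, 148 of 10981 other RNAs (1.35%) were called for replicate number, which met the bound set beforehand for a batch shared by same-numbered libraries. Of these 12 RNAs 12 were called too, which tests nothing, since they were described by that difference. Shared reads and a batch may both apply. No biological explanation was tested, since the design names none for the numbers.

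The Zhx3-Gm16751 contact rose by as much as contacts within Zhx3, with a difference in log2 change of 0.01 (0.0111, 95% interval −1.05 to 1.07). Both may follow the same Zhx3 RNA, but a rise of all Zhx3 contacts is not shown: Zhx3-Chd6 fell (−3.40), Gm42418-Zhx3 was at 0.06, and the Zhx3 total over between-RNA pairs was at 0.14 (adjusted p = 0.710). All 3 other partners of Gm16751 (Chd6, Gm42418 and Gm26917) were also partners of Zhx3, and 12 of 12 of their counts were no higher with Gm16751 than with Zhx3. Reads of 1 locus counted for 2 overlapping genes cannot be told apart from a true contact here, because the location and strand of Gm16751 were not used and partners are few. A change in the contact itself on differentiation stays open and was not tested.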
